A study of Mus musculus with 14 samples.

How the data were processed

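RARα occupancy was profiled by CUT&RUN in 266-6 cells, a mouse pancreatic acinar cell line. Per the labels, cells spent 24 h in stripped medium and then 24 h with ligand or DMSO, and libraries were amplified for 9 cycles. The labels name 14 samples in 5 treatments: DMSO (3), 9-cis retinoic acid (3), AM580 (2), CD3254 (3) and AM+CD (3). The labels of all replicates of a treatment name the same peak list, so 5 lists were analysed and each list counted as 1 sample. Peak names in the ligand lists begin with an abbreviation of the treatment followed by 1 (9C1, AM1, CD1 and CD-AM1). Those in the DMSO list begin with NL1, which does not abbreviate its label. Whether a list stands for replicate 1, for replicates pooled before peak calling or for replicates combined afterwards is not given in the sources used here.

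Per the submitters' processing notes, the tools included FastQC, Bowtie2 2.5.1, SAMtools 1.18, MACS2 2.2.7.1 and bedtools, with genome build mm10. The order of the steps, the control, the q threshold and the treatment of duplicate or multiply mapping reads are not given in the sources used here. Each deposited list is in MACS2's narrowPeak layout and gives, for every peak, its position and summit. It also holds the authors' fold enrichment of the summit over the local background, a ratio. The deposited −log10 p and −log10 q of each peak were used to rank and filter peaks within a list. The deposited score, which follows 10 times the −log10 q as a whole number, was not used further. A fold or −log10 q belongs to its own list and was not compared between lists. Positions are printed with 1-based starts on mm10.

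Peak names within a list run in genome order and have gaps, so each list is part of a longer call. The highest number and the gaps gave the least number of peaks each call had held and the stretches of the genome where peaks had been removed. Each summit's whole-number pileup and local background were recovered from its fold and −log10 p, given as (pileup + 1) / (background + 1) and the upper Poisson tail that MACS2 computes. In all 1529 peaks the nearest whole pileup met the −log10 p within a relative 0.0000123, under the tolerance of 0.0002 set for calling a pileup recovered. The lowest background in a list, shared within 0.001 fragments per base by 10 to 53 peaks, was taken as that call's background coverage in fragments per base and served as its depth. The number of reads per library is not given in the sources used here. On simulated data, 500 of 500 summits returned their exact pileup.

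Lists were compared by the share of the peaks of one that met a peak of the other by at least 1 bp, with a 95% Wilson interval. Each share was set against 10000 random placements of the first list's peaks on their own chromosomes in a one-sided permutation test. The placement range of a chromosome ran from the first to the last gene or peak on it, since chromosome lengths were not used here. Benjamini-Hochberg adjustment covered the 20 ordered pairs of lists. The test was tested on simulated data, with 40 lists of 286 random peaks each set against the CD3254 list. These peaks were placed as in the test itself, so the simulation checks the procedure and not the placement. With 0% of shared peaks planted, 9.09% met the CD3254 list by chance, and 1 of 40 passed 0.05. With 5% planted, 39 of 40 passed, and with 50% planted, 40 of 40 passed. Differences between shares have Newcombe 95% intervals. These treat the shares as independent, although both are scored against the same DMSO list and the lists compared have many places in common. Neighbouring peaks are not independent and 1 list stands for each treatment, so the intervals cover counting error and the tests compare these lists, not the conditions.

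Overlapping peaks of the 5 lists were joined into union regions. A region was placed in 1 of 4 classes in this order. The first was 8 high-signal regions (satellite, ribosomal and mitochondrial sequence) listed from general knowledge of the mouse genome before the data were examined. The others were contigs, dense clusters of at least 3 regions linked by gaps of at most 100 kb, and single regions. The mitochondrial genome was among the high-signal regions, so its regions fell in the first class. The clusters were defined after the lists had been seen.

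Genes came from a RefSeq table of GRCm38.p6, the assembly that mm10 names, with 49997 genes of which 21900 are protein coding. The table gave gene spans without strand or exons. The planned share of peaks near transcription start sites was therefore replaced by the share in a gene span and the share within 1000 bp of either end of a gene. Both were set against 1000 random placements and adjusted over the 5 lists. For the same reason exon, intron and UTR were not told apart. The planned search for direct repeats of the receptor half-site needs a genome sequence and was not run. Gene lists fixed before the data were examined, 11 in all, were scored by the number of genes with a peak in or within 50 kb of the span. The count was set against 10000 random lists of the same number of protein-coding genes, and against lists also matched on span length in 10 bins.

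The regions named in the text follow a rule fixed before the data were examined. It takes the 5 peaks of highest fold in each list outside the 8 high-signal regions, and up to 10 regions in all lists by mean rank of −log10 q. For each ligand it takes up to 15 peaks that met no DMSO peak and up to 5 DMSO peaks that met no peak of that ligand, by −log10 q. It also takes up to 10 regions each of 3 list combinations and every fixed-list gene with a peak within 50 kb. A region carries the name of the nearest protein-coding gene by span if that gene is within 50 kb, which replaced the distance to the start site. Names outside the rule are marked as chosen after the values were seen.

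The alternatives tried were a 50% reciprocal overlap, summits within 200 bp, peaks within 1000 bp, a threshold of at least 2 times the lowest −log10 q of a list, lists trimmed to the 200 best peaks, main chromosomes, no high-signal regions, and placement within 50 kb. Chosen after seeing the data were the alternatives without clusters and contigs or without the 9-cis retinoic acid list, all recounts of regions, and all alternatives for gene shares and gene lists. The last replaced planned ones on start sites. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.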

Results

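CUT&RUN releases the DNA around an antibody-bound protein with a tethered nuclease. It was used here against retinoic acid receptor alpha (RARα), which binds DNA as a heterodimer with a retinoid X receptor (RXR). The study asks how ligands of the partners of this heterodimer bear on each other across the genome. AM580 is an agonist selective for RARα and CD3254 an agonist selective for RXR, while 9-cis retinoic acid activates receptors of both families. The treatment labelled AM+CD is not spelled out in the labels, and its peak names join the abbreviations of the AM580 and CD3254 lists. All treatments lasted 24 h. Doses are not given in the sources used here.

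The lists held 286 peaks with DMSO, 200 with 9-cis retinoic acid, 323 with AM580, 493 with CD3254 and 227 with AM+CD, 1529 in all. Median peak width lay between 421 bp with AM580 and 535 bp with AM+CD. Background coverage, the measure of depth, was 1.32 fragments per base with DMSO, 0.544 with 9-cis retinoic acid, 0.985 with AM580, 2.36 with CD3254 and 2.13 with AM+CD. The DMSO list entered all 4 ligand comparisons. No treatment has replicate lists, so differences between lists have no replicate check, and the absence of a peak means only that none was listed there.

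**Figure D1:**
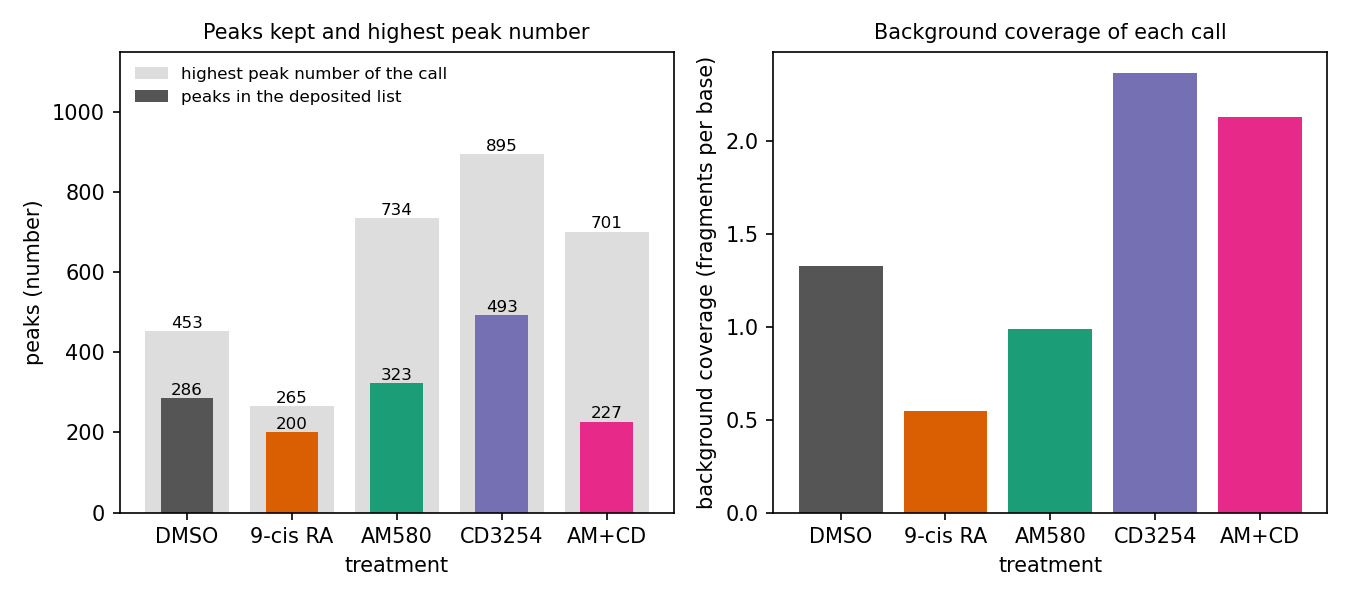
Left, peaks in each deposited list (narrow bars) in front of the highest peak number in that list (wide bars), by treatment; right, background coverage of each call in fragments per base. The AM+CD call reached number 701 and its list kept 227 peaks, while the DMSO call reached 453 and its list kept 286.

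The peaks joined into 551 union regions, of which 158 had a peak in every list and 219 in a single list. The regions ranked highest across the 5 lists were repeat sequence. The first was a major satellite block on chromosome 2 (98666269 to 98667381, fold 17.0 in DMSO). The next were a repeat on chromosome 9 (35305222 to 35305678, fold 35.7, 29265 bp from Rpusd4) and a repeat on chromosome 14 (19416871 to 19419382, fold 15.2). A nuclear copy of mitochondrial DNA within the span of Chl1, a neural cell adhesion gene (chromosome 6, 103649049 to 103649414, fold 38.8), came next. The other 6 of the 10 lay in the satellite block of chromosome 9 between 3000022 and 3038309.

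Outside the fixed high-signal regions, the 5 peaks of highest fold were the same places in the DMSO, CD3254 and AM+CD lists, while AM580 shared 3 of them and 9-cis retinoic acid 2. The region on chromosome 13 at 9011688 to 9012240, 15572 bp from Gtpbp4, a gene for a nucleolar GTPase of ribosome assembly, was among the 5 highest in every list. Its fold was 30.6 with DMSO, 23.1 with 9-cis retinoic acid, 36.4 with AM580, 32.5 with CD3254 and 32.1 with AM+CD, each relative to its own background. A region on chromosome 12 (3109872 to 3110215, no gene within 50 kb) led the DMSO list at 38.9 and the AM580, CD3254 and AM+CD lists at 42.9, 39.6 and 40.3. It had no peak in the 9-cis retinoic acid list. The same 4 lists shared a region on the X chromosome (143483005 to 143483301) 35065 bp from Pak3, a p21-activated kinase gene, with folds of 32.7 to 36.8. In the 9-cis retinoic acid list, high folds stood in the spans of Cldn34d (X chromosome, 76598550 to 76599220, 23.3), Mdga2 (chromosome 12, 67059167 to 67059927, 22.4) and Atrnl1 (chromosome 19, 58113265 to 58113705, 22.2). All 3 regions had a peak in every list.

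Of the regions in all lists, 90 of 158 (57.0%, 95% Wilson interval 49.2 to 64.4) were in the fixed high-signal regions, on contigs or in dense clusters. The largest cluster held 32 regions on chromosome 8 between 20275231 and 20682577, around Gm15319 and Gm21119. A cluster of 15 lay at 14914439 to 15054880 on chromosome 5, around Speer4e, a member of a duplicated testis-expressed family. Another of 14, at 15462575 to 15712262, lay around Speer4c. A cluster of 6 on chromosome 10 (58221687 to 58239725) lay around LOC100504180 and Duxf3, a double homeobox gene. These clusters and their genes were chosen after their values were seen, and some clusters larger than the one on chromosome 10 are not named. In every list between 49.5% (9-cis retinoic acid) and 59.4% (DMSO) of peaks fell in these classes.

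**Figure D2:**
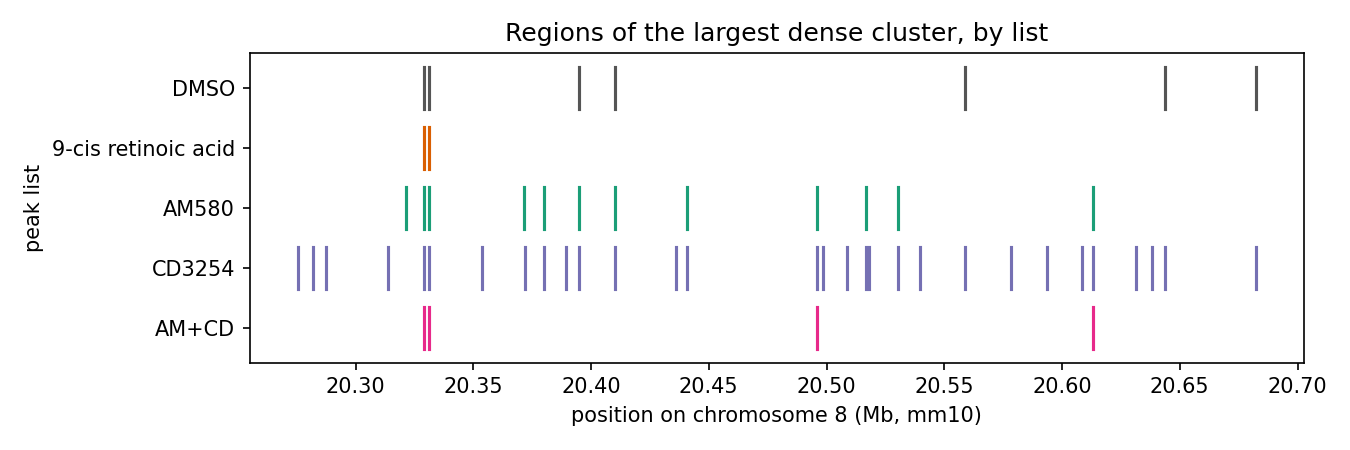
Positions of the 32 regions of the largest dense cluster on chromosome 8 (x axis, Mb), with 1 tick for each region in which the list on the y axis had a peak. The CD3254 list had a peak in 30 of them, AM580 in 12, DMSO in 7, AM+CD in 4 and 9-cis retinoic acid in 2.

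Peaks on the main chromosomes met protein-coding gene spans less often than random positions did in all 5 lists. The share was 24.5% (19.3 to 30.7) with DMSO against 40.7% at random, 24.7% with 9-cis retinoic acid, 26.6% with AM580, 25.4% with CD3254 and 25.1% with AM+CD. Each gave a one-sided permutation p = 0.001, the smallest that 1000 placements can give, and an adjusted p of 0.001. Without the clusters, contigs and high-signal regions the shares were 37.1%, 32.7%, 36.8%, 35.0% and 37.3%, and none passed (adjusted permutation p = 0.23 to 0.35). Within 1000 bp of a gene end lay 12.3% (8.80 to 16.9) of AM580 peaks against 7.75% at random (one-sided permutation p = 0.007, adjusted 0.035). This fell to 7.64% (p = 0.53 by the same permutation test) without the clusters, and no other list passed adjustment.

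9-cis retinoic acid was compared with DMSO to ask where a ligand of both receptor families was accompanied by RARα peaks that the vehicle lacked. Of its 200 peaks, 173 met a DMSO peak (86.5%, 81.1 to 90.6) and 27 did not. Trimmed to 200 peaks in each list the share was 74.0%, and regions in this list alone went from 24 to 37. The 9-cis retinoic acid list already held 200 peaks, so trimming shortened only the other lists and its share could not rise. The 27 included a peak in the span of Rarb, the gene of RARβ and a known retinoic acid target (chromosome 14, 16859535 to 16859838, fold 6.61, −log10 q 5.39). This peak stood 429 kb and 222 kb from the ends of a gene 651 kb long, and rested on a summit pileup of 10 fragments. Others were within Clasp2, a microtubule plus-end binding gene (chromosome 9, 113756388 to 113756897, fold 7.42), within Nek1, a kinase gene (chromosome 8, 61001548 to 61001886, 6.48), and within Peak1, a pseudokinase gene (chromosome 9, 56223572 to 56224050, 7.07). Near genes of nuclear regulators they lay 35753 bp from Satb1 (chromosome 17, 51869043 to 51869555, 7.13), 32543 bp from Hsf2 (chromosome 10, 57450837 to 57451223, 6.81) and 11964 bp from Gpbp1 (chromosome 13, 111502092 to 111502404, 7.49).

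Clasp2 and Satb1 also had an AM580 peak and Peak1 an AM580 and an AM+CD peak, while the other 24 regions were in no other list. These 24 had −log10 q from 1.60 to 9.57 and summit pileups of 6 to 13 fragments. The 2 with the highest −log10 q, 9.57 and 9.43, had no gene within 50 kb (X chromosome, 75942498 to 75942832, and chromosome 16, 86077482 to 86077816). Of the 279 DMSO regions, 110 had no 9-cis retinoic acid peak. Leading them was the region at 3109872 on chromosome 12, with a DMSO summit pileup of 7301 fragments. The next lay in the fixed high-signal regions of chromosomes 2, 14 and 9 (starts 98662264, 19415735 and 3004514), followed by the one near Pak3. The shared 173 peaks compared with a mean of 14.1 at random positions (one-sided permutation p = 0.0001, the smallest that 10000 placements can give, adjusted 0.0001). The 9-cis retinoic acid call was the shallowest of the 5, but scaled to its coverage 92 of the 110 DMSO regions would still have passed the lowest −log10 p of its list. With each pileup at its lower limit for a probability of 1e-06, 35 would have. At 59 of the 110 no 9-cis retinoic acid peak number is missing. Missing numbers leave room for at most 27 (24.5%, 17.5 to 33.4), against 28.4% at random. Selection of peaks after the call therefore does not account for most of the 110. Most of the 110 were not single regions. Those held by DMSO, AM580 and CD3254 alone numbered 46, of which 16 were single. Of the 36 also held by AM+CD 16 were single, and of the 20 held by DMSO and CD3254 alone 7 were. Whether these places were receptor sites was not tested.

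AM580 was compared with DMSO for the effect of an RARα agonist alone. Of its 323 peaks, 248 met a DMSO peak (76.8%, 71.9 to 81.1) and 75 did not. Leading those 75 was a region on chromosome 1 (157877238 to 157877610, fold 20.2) with no gene within 50 kb. The next stood in the span of Slc22a29, an organic anion transporter gene (chromosome 19, 8252234 to 8252549, 17.7). Others lay 32311 bp from Epm2a, the gene of the glycogen phosphatase laforin (chromosome 10, 11491975 to 11492282, 12.3), and within Gtf2ird1, a transcription factor gene (chromosome 5, 134378867 to 134379210, 10.5). The transcription factor gene Sp3 had one at 32289 bp (chromosome 2, 73012735 to 73012998, 10.1), Tbca, a tubulin folding gene, at 14160 bp (chromosome 13, 94857083 to 94857426, 10.6), and Zfp629 at 3009 bp (chromosome 7, 127618794 to 127619280, 10.6). All of these named regions also had a CD3254 peak. A region on chromosome 4 (78513221 to 78513560, fold 11.6, no gene within 50 kb) did not and was in the AM580 list alone. Its −log10 q of 19.6 was above the 17.8 of the region at Gtf2ird1. In all, 26 regions were in the AM580 list alone.

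In the other direction 32 DMSO regions had no AM580 peak, led by one in the fixed high-signal regions (chromosome 9, 3004514 to 3004803). They included a region 14734 bp from Dpy19l2 (chromosome 9, 24542015 to 24542313, fold 30.2 in DMSO), one in the span of Sos2, a Ras exchange factor gene (chromosome 12, 69654056 to 69654354, 20.5), and one in the span of C1qbp (chromosome 11, 70979398 to 70979652, 15.5). The share of AM580 peaks that met DMSO was 6.49% at random (one-sided permutation p = 0.0001, adjusted 0.0001). Trimmed to the 200 best peaks of each list, it was 91.5%.

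CD3254 was compared with DMSO for the effect of an RXR agonist on RARα. Its list contained nearly the whole DMSO list: 284 of 286 DMSO peaks met a CD3254 peak (99.3%). Of its own 493 peaks, 279 met a DMSO peak (56.6%, 52.2 to 60.9) and 214 did not. The highest −log10 q of the 214, 273, belonged to a region in the span of 2210408I21Rik (chromosome 13, 77438910 to 77439186, fold 28.1). Next were a region on chromosome 16 with no gene within 50 kb (98107444 to 98107698, 28.8) and one in the span of Pknox1, a TALE homeobox gene (chromosome 17, 31570414 to 31570674, 22.3). Litaf, an endosomal protein gene (chromosome 16, 10975068 to 10975320, 20.8), and Mamdc2 (chromosome 19, 23357428 to 23357689, 18.2) each held one in their span. The regions at Pknox1, Litaf and Mamdc2 were in no other list.

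The regions of the CD3254 list alone numbered 163, with a median −log10 q of 10.6 and a range of 2.09 to 219. Dense clusters held 67 of them and single positions 81. At random 4.88% of CD3254 peaks met DMSO (one-sided permutation p = 0.0001, adjusted 0.0001). Trimmed to 200 peaks in each list, the share rose to 90.0% and 15 regions were left in CD3254 alone.

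AM+CD was compared with DMSO and then with each single agonist. Of its 227 peaks, 203 met a DMSO peak (89.4%, 84.8 to 92.8), 207 an AM580 peak (91.2%, 86.8 to 94.2) and 219 a CD3254 peak (96.5%, 93.2 to 98.2). Trimmed to 200 peaks in each list the order turned, with 87.5%, 87.0% and 83.0%. Among the 24 without DMSO, the leading region was again the one in the span of 2210408I21Rik (fold 27.1). The next by −log10 q (70.1) lay in a dense cluster on chromosome 17 (3030469 to 3030926, fold 5.04), with no gene within 50 kb. Single regions included those in the spans of Gtf2ird1 (10.9) and Peak1 (7.04) and 15781 bp from Jazf1 (chromosome 6, 53084405 to 53084875, 7.07). Several others were in dense clusters, such as one in the span of Duxf3 (chromosome 10, 58231794 to 58232575, 4.79), or on contigs. The AM+CD list alone held 5 regions, with −log10 q of 1.77 to 8.52. One was in the span of Fetub, the fetuin B gene (chromosome 16, 22928509 to 22928838, fold 5.44), and one 20221 bp from Rchy1, a ubiquitin ligase gene (chromosome 5, 91928245 to 91928621, 5.76).

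Of 291 regions held by both AM580 and CD3254, AM+CD lacked 86, of which 53 were also in DMSO and 33 in no other list. The AM+CD list kept 32.4% of the peak numbers of its call. Among DMSO regions without AM+CD, the leading one was 9350 bp from Fam107a (chromosome 14, 8286634 to 8286920, fold 23.5 in DMSO). The next lay in a dense cluster of 11 regions, 27665 bp from Sfi1, a centriole gene (chromosome 11, 3103726 to 3104185, 7.08). Both had AM580 and CD3254 peaks. At random 7.14%, 7.47% and 8.32% of AM+CD peaks met DMSO, AM580 and CD3254 (one-sided permutation p = 0.0001 and adjusted 0.0001 for each).

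The agonists were set side by side at the matched 24 h, with doses not given. No region was in all 4 ligand lists and absent from DMSO. The 75 AM580 peaks and 214 CD3254 peaks without DMSO shared 44 peaks, among them those at Slc22a29, Epm2a, Sp3 and Gtf2ird1. CD3254 and 9-cis retinoic acid shared 0 of these peaks, and AM580 and 9-cis retinoic acid shared 3, at Clasp2, Satb1 and Peak1. All these sets lack a peak in the same DMSO list, so a peak removed from that list would count as shared between ligands, and no chance value is given.

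The share of peaks that met DMSO was higher with AM580 than with CD3254 by 20.2 percentage points (Newcombe 95% interval 13.7 to 26.3). Trimmed to 200 peaks the shares were 91.5% and 90.0%, and the interval of their difference (-4.31 to 7.35) includes 0.

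9-cis retinoic acid was compared with AM+CD because both address RARα and RXR, on the reading that AM+CD holds both agonists. Of the 9-cis retinoic acid peaks, 165 of 200 met an AM+CD peak (82.5%, 76.6 to 87.1) against 6.06% at random (one-sided permutation p = 0.0001, adjusted 0.0001). No region was in these lists and in no other. The region in the span of Peak1 was the single one they shared that DMSO lacked, and AM580 held it too. The Rarb region was in the 9-cis retinoic acid list alone, and the 2210408I21Rik region in the AM+CD and CD3254 lists alone. The shares that met DMSO differed by -2.93 points (9-cis retinoic acid minus AM+CD, -9.31 to 3.26). The difference was -13.5 points (-21.1 to -5.80) in lists trimmed to 200 peaks and -13.0 points (-23.8 to -1.93) without clusters, contigs and high-signal regions. Trimming left the 9-cis retinoic acid list of 200 whole and shortened the DMSO list, so its share could not rise. Leaving out the clusters, contigs and high-signal regions removed only 9-cis retinoic acid peaks that met DMSO. Neither interval is therefore a measure of a difference between the ligands.

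Of 28 retinoic acid receptor target genes, among them Cyp26a1, Dhrs3 and Stra6, 0 had a peak within 50 kb with DMSO, AM580, CD3254 or AM+CD (0%, 0 to 12.1). With 9-cis retinoic acid 1 did (Rarb, 3.57%, 0.633 to 17.7), and 14.0% of random gene lists, or 14.6% matched on span length, had as many. Within 100 kb, Fgf8 was added in every list, through a region 86.1 kb away that lies in the span of Fbxw4 (chromosome 19, 45649935 to 45650375 in AM+CD). Both names are outside the rule and were chosen after their values were seen.

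Rarb was also the sole hit, in the 9-cis retinoic acid list, among 28 nuclear receptors and co-regulators. There was no peak within 50 kb of any of the 20 retinoid metabolism and transport genes, 18 LXR and PPAR targets or 22 Hox and related homeobox genes. The same held for the 19 acinar enzymes that were in the gene table and the 10 acinar transcription factors, such as Ptf1a and Nr5a2. Of the lists set for comparison, the 10 ductal, 11 endocrine and 11 stellate and fibroblast genes had none. Random gene lists averaged 0.053 to 0.314 hits for these lists and 0.151 to 0.407 for the receptor targets. A count of 0 can therefore not be told from that of random genes. For the receptor targets, the counts give no evidence that any of the lists marks these genes. Of 16 housekeeping genes 1 had a peak, Tuba1b at 3230 bp with DMSO (chromosome 15, 98937620 to 98938077, fold 7.23), and also with AM580 (7.68) and CD3254 (9.18). No count in any list was reached by fewer than 12.8% of random gene lists.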

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

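The tests that left out clusters and contigs, the list without 9-cis retinoic acid, all recounts of regions and all gene share and gene list alternatives were chosen after the data had been seen. In each of the 63 recomputed overlaps of the 7 main comparisons the share stayed above random placement (one-sided permutation p = 0.0005, the smallest that 2000 placements can give). Placement took no account of repeats or of where reads gather, so passing it shows shared positions, not shared receptor binding. The shares ranged from 51.8% (CD3254 in DMSO, main chromosomes) to 97.3% (AM+CD in CD3254, stricter threshold).

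With the 200 best peaks of each list, union regions numbered 282, regions without DMSO 84, CD3254 alone 15, AM580 alone 6, 9-cis retinoic acid alone 37, DMSO alone 3, and all ligands without DMSO 1. The difference between AM580 and CD3254 in the share that met DMSO was then 1.5 points and that between 9-cis retinoic acid and AM+CD -13.5 points. The construction of equal lengths, which trims the longest list the most, accounts for the lower CD3254 count. It also leaves the 9-cis retinoic acid list of 200 whole while the DMSO list is shortened, so the share of that list that met DMSO could not rise.

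Without contigs, high-signal regions and clusters, 116 DMSO, 101 9-cis retinoic acid, 144 AM580, 217 CD3254 and 102 AM+CD peaks were left. Union regions numbered 270, of which 68 were in all lists, 81 in CD3254 alone, 155 without DMSO and 0 in DMSO alone. The difference between 9-cis retinoic acid and AM+CD was -13.0 points. Every 9-cis retinoic acid peak without DMSO was a single region, so only peaks that met DMSO were removed from that list. Of those left, 74 of 101 met DMSO, against 88 of 102 with AM+CD. Why the peaks without DMSO were all single regions was not tested. The share within 1000 bp of a gene end turned from above to below random with CD3254 (6.91%), DMSO (5.17%) and AM+CD (5.88%). Of 30 recomputed gene shares 23 kept their side of 0.05 for the permutation p before adjustment, which CD3254 at gene ends had passed in the full list. Without the 9-cis retinoic acid list, 11 regions were in the 3 remaining ligand lists and not in DMSO. Of all 62 recomputed region counts 49, and of all 20 recomputed peak counts 15, stayed within 1.5 times.

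No paired analysis was possible because the lists hold no values per replicate, and leaving out a replicate was not run for the same reason. The direct repeat and start site alternatives were not run.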

Other observations

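The tests of depth, of low pileups and of near-identical copies, and the tests of why the AM+CD list was short, were chosen after the results had been seen. The use of missing peak numbers for the regions of the CD3254 and 9-cis retinoic acid lists was set before its values were known.

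Beyond the comparisons, the starts of the chromosomes held part of the regions, for which no random expectation was computed. Of the 551 union regions, 75 (13.6%, 11.0 to 16.7) lay on 11 chromosomes before position 3300000, next to the centromeric gap with which mouse chromosomes start. The share was 18.4% (13.1 to 25.1) of regions in all lists and 0 of 24 in the 9-cis retinoic acid list alone. A single unplaced contig held 23 regions, of which 18 were in all lists. In the cluster at 181917359 to 182013201 on chromosome 2, all 6 regions had a DMSO, AM580 and CD3254 peak. Among the 4 regions at Tmem267 on chromosome 13 (119596687 to 119602990) all were in every list.

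Single regions of the CD3254 list alone included one in the span of Rora, an orphan nuclear receptor gene (chromosome 9, start 69099577), one in Cdk6 (chromosome 5, start 3479855) and one in Il34 (chromosome 8, start 110799001). Those of AM580 alone included one in Gabbr2 (chromosome 4, start 46777812). Those shared by AM580 and CD3254 included one in Gpt2 (chromosome 8, start 85499595). These names, and the cluster at Tmem267 and that on chromosome 2, were chosen after their values were seen. Of the 163 regions of the CD3254 list alone, 39 (23.9%, 18.0 to 31.0) lay in a protein-coding gene span. The genes named from them are examples and not evidence of a ligand effect.

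Why CD3254 alone held 163 regions was weighed first. For lower depth of the DMSO call, each pileup was set to its lower limit for a probability of 1e-06 and scaled to DMSO coverage. At that limit 29 of the 163 (17.8%, 12.7 to 24.4) still passed the lowest −log10 p of the DMSO list. Lower depth does not account for those 29. At most 10% was taken as compatible with depth for the whole set, a limit chosen after the results had been seen. The interval treats regions as independent, although dense clusters held 67 of the 163, so it does not settle the whole set. Selection of DMSO peaks after the call may account for part, since 167 DMSO peak numbers are missing and leave room for at most 64.4% (56.8 to 71.4) of the regions, above the 52.8% that bounded random positions. At 37 of the 163 no DMSO number is missing, so the DMSO call had no peak there. Near-identical copies stay open, with 50.3% (42.7 to 57.9) of the regions in clusters, contigs or high-signal regions. Of all CD3254 peaks 56.0% lay there, and of regions in all lists 57.0%, so this share does not set the 163 apart. An effect of the RXR agonist also stays open, as 1 list per treatment leaves it untested.

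For the 24 regions of 9-cis retinoic acid alone, Rarb among them, 0% (0 to 13.8) lay in clusters, contigs or high-signal regions. This cannot decide on near-identical copies, because the classes use no measure of repeated sequence. The region at 3109872 on chromosome 12, with a DMSO summit pileup of 7301 fragments, also counts as a single region. Sampling noise of low pileups stays open, because with pileups of 6 to 13 no region could have passed at the lower limit used. Missing DMSO numbers leave room for up to 79.2% (59.5 to 90.8) of them, within the 87.5% that bounded random positions. At 5 of the 24 no DMSO number is missing. A response to the ligand stays open and untested.

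The AM+CD list was shorter than the DMSO list, with 227 against 286 peaks. Lower depth of the AM+CD call is argued against, since its background coverage was 1.61 times that of DMSO. Selection of peaks after the call is a candidate explanation: 32.4% (29.0 to 35.9) of its 701 peak numbers were kept, against 63.1% (58.6 to 67.4) of 453 for DMSO. All 76 DMSO regions without an AM+CD peak lay beside missing AM+CD numbers that were enough to hold them (85.0% at random, up to 92.1%). What the removed peaks were, and whether AM+CD replicates differed more from each other, is open.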
